A study of Mus musculus with 3 samples.

How the data were processed

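Total RNA from 3 mouse cell populations was measured on 3 Affymetrix expression arrays, 1 array per population. The populations were embryonic fibroblasts (MEF), induced neural stem cells (iNSC) and control neural stem cells (cNSC), all labelled as strain C3H at embryonic day 13.5. Per the labels' protocols, 100 ng of total RNA was reverse transcribed and copied by in vitro transcription into biotin-labelled antisense RNA. The value table deposited by the authors holds log2 expression values, 1 column per array and 45141 probe sets. The log2 unit was read from the range of the values. RMA, Affymetrix Expression Console and Partek are named in the submitters' processing notes, with no version and no statement of what each was used for. A genome build is not given in the sources used here, and no coordinates are reported.

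The 104 control probe sets (names starting with AFFX) were kept apart, which left 45037 probe sets. Gene names came from a table of the platform's annotation that listed 29449 probe sets. Of these, 28898 had 1 gene symbol, 551 had several and 0 had none, and only those with 1 symbol were used. Of the used probe sets, 16139 had no single listed name and were not analysed by gene. Gene identifiers of 28689 probe sets matched the RefSeq gene table of GRCm38.p6, which altered 0 symbols. Each gene was represented by the probe set with the highest mean over the 3 arrays, giving 17097 genes, of which 9917 had 1 probe set and 7180 had several.

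With 1 array per population there was no replicate, so no p-value, standard deviation or replicate check could be given, and the number of arrays limits the precision.

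Differences were taken between log2 values as deposited. A gene was called apart when the 2 arrays differed by at least 4-fold (2 log2 units) and the brighter array was at or above a floor, the median of all probe sets over the 3 arrays (4.57). Higher and lower below refer to this rule of size, or to a stated value. For genes with several probe sets above the floor, the direction of the others was checked, and the spread of differences among probe sets of a gene was the only spread available.

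Gene lists, 34 in all with 576 distinct genes of which 509 were measured, included cell types that a culture could hold besides the intended ones. The median difference of each list was set against 10000 random lists of the same size matched on mean expression in 20 bins, and its percentile describes these arrays only. A list is said to lie outside the central 95% when its median falls beyond the range that holds that share of the random medians.

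Genes were named by a rule. In each comparison it took the 12 most higher and the 12 most lower genes that met the rule of size, had a functional symbol and had no other probe set above the floor running the opposite way by 2-fold or more. It also took the transduced factors, and from each list up to 4 members with the largest absolute difference and up to 2 measured members that were not apart. The gene lists, this rule, the rule of size and the alternatives were fixed before the data were examined, apart from those stated to have been added later.

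Both comparisons against MEF share the MEF array. Unchanged cells were therefore simulated 100 times against it, and the overlap of independent lists was computed. The calling and list steps were tested on simulated data over 17097 genes with a noise of 0.3 log2 units. This noise was a chosen value and was not measured on these arrays. Differences of probe sets of 1 gene had a spread of 0.74 for iNSC against MEF. That spread was 0.63 for cNSC against MEF and 0.59 for iNSC against cNSC. The counts that follow hold for a noise of 0.3 only and do not give a rate of false calls for these data. Among 16897 unchanged genes, 0 were called for iNSC against MEF, 1 for cNSC against MEF and 0 for iNSC against cNSC. Changes of 8-fold or more were called in 97.3%, 98.7% and 98.0% of cases, in the same order. The test was first set to allow no call among unchanged genes and was relaxed after that 1 call was seen.

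Alternatives were the mean of all probe sets of a gene, leaving out probe sets with _x_at, _s_at or _a_at endings, quantile normalization, centring on the median, no floor, a floor at the 75th percentile (6.37), and thresholds of 2-fold and 8-fold. Correlations were also taken over genes above the floor and over all probe sets, and list shifts over members above the floor. Scaling to the 18 hybridization control probe sets was added after seeing that these read higher on the cNSC array. Shared genes were also counted among genes above the floor on both cNSC and MEF, added after seeing that many lower genes read below it. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.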

Results

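The study set induced neural stem cells beside their starting cells and beside control neural stem cells, under a title on the treatment of spinal cord injury. The fibroblasts (MEF) came from mouse embryos at day 13.5 and served as negative control. The induced cells (iNSC) were fibroblasts given 4 factors by retrovirus, Sox2, Klf4, c-Myc and Brn4 (gene Pou3f4), whose clusters were seen 4 to 5 weeks later and expanded. Control neural stem cells (cNSC) served as positive control, and both stem cell populations grew with EGF and bFGF. Any difference in culture conditions between MEF and the stem cells cannot be told apart from cell type here. Each population had 1 array, so every difference below lacks a replicate check. The dimmer array read below the floor of 4.57 for 19 of the 24 named genes for iNSC against MEF, 20 of 24 for cNSC against MEF and 12 of 24 for iNSC against cNSC, so the sizes and order of those differences are not exact. The same limit holds for list members whose dimmer array read below the floor, and for list medians that rest on them.

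The 3 arrays did not share a distribution. The 75th percentile of all probe sets was 6.73 on the MEF array, 5.97 on the iNSC array and 6.44 on the cNSC array. Over all genes the median difference was -0.29 for iNSC minus MEF, 0.03 for cNSC minus MEF and -0.26 for iNSC minus cNSC. Over genes with the brighter array at or above the floor it was -0.55, -0.09 and -0.38, in the same order. Gene values below are to be read against these shifts, and those of expressed genes against the latter. Hybridization control probe sets, which report RNA added at hybridization, were higher on the cNSC array than on the MEF array by a mean of 1.17 over 18 probe sets, and differed by -0.13 between iNSC and MEF. Nonspecific background probe sets, grouped by GC content, averaged 3.58 on MEF, 3.11 on iNSC and 3.68 on cNSC.

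**Figure D1:**
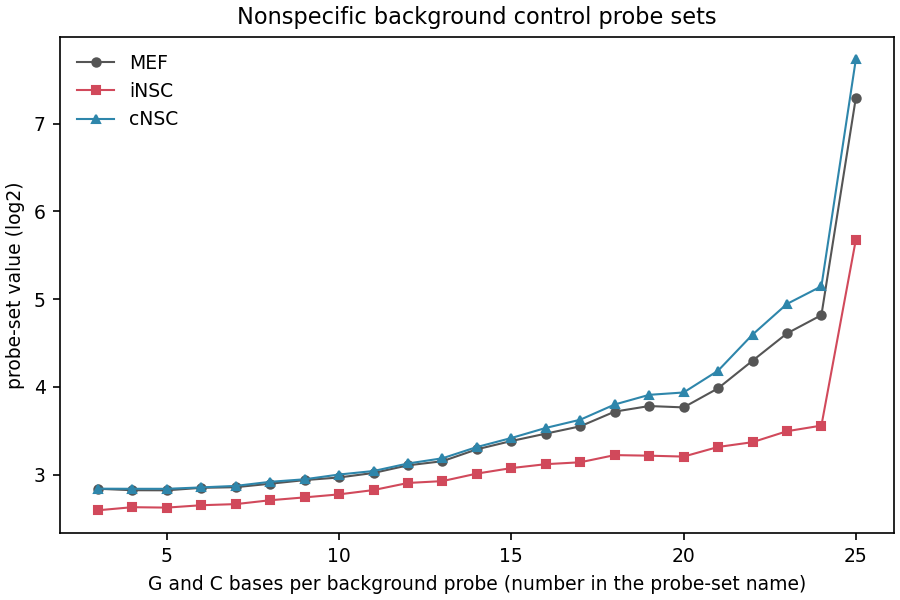
Log2 value of 23 nonspecific background probe sets (y axis) against the number of G and C bases given in the probe-set name (x axis), 1 line per array. The iNSC line lies below the MEF and cNSC lines throughout, and at 25 bases it reads 5.68 against 7.29 on MEF and 7.73 on cNSC.

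The transduced factors were read in every array first. Sox2, a regulator of neural stem cell identity, read 5.57 in MEF, 10.49 in iNSC and 11.52 in cNSC. Pou3f4 read 4.53, 6.87 and 8.28 in the same order. Klf4 was highest in MEF at 9.75 and read 5.84 in iNSC and 6.23 in cNSC, while Myc read 8.57, 8.30 and 8.52. Whether these probe sets also detect the retroviral transcripts is not known here, so these values do not check the labels.

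Comparing cNSC with MEF gave the scale on which the induced cells were read. Aqp4, a water channel of astrocytes, was 8.23 log2 units higher in cNSC, Olig1 8.22, Aldoc 7.78, Trim9 6.77, Gpm6a 6.66 and Phyhipl 6.61. Olig2 was 6.43 higher, Rfx4 6.35, Ncan 6.24, Adgrb3 6.19, Ecrg4 5.96 and Sox2 5.95. S100a6 was lower at -9.08, with Col3a1, a fibrillar collagen, at -7.90, Ptgs2 at -7.83, Ccn2 at -7.64, Lgals3 at -7.28 and Postn at -7.24. Bgn (-7.18), Lyz2 (-7.10), Igf2 (-6.98), Cdh11 (-6.93), Grb10 (-6.88) and Tpm2 (-6.85) followed, though another Tpm2 probe set differed by -0.05.

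Of 11840 genes at or above the floor on at least 1 of these arrays, 1043 were apart in cNSC, 334 higher and 709 lower. Several probe sets were above the floor for 411 of them, and in 377 all ran in the same direction. All were at least 4-fold apart in 163 of the 411, so other probe sets often gave smaller differences. Scaling to the hybridization controls, added after seeing the data, gave 128 higher and 2417 lower, with a median of all genes of -1.14.

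Comparing iNSC with MEF asked how the transduced cells differed from the MEF culture. Olig1 was 7.12 higher in iNSC, Aldoc 6.79, Olig2 6.63, Aqp4 5.33, Ncan 5.23 and Rfx4 5.19. Gpm6a (5.16), Sox8 (5.05), Sox2 (4.92), Slc15a2 (4.91), Ecrg4 (4.85) and Fabp7 (4.84) completed the most higher genes. Other probe sets differed by -0.17 for Ncan, 0.07 for Slc15a2 and 0.20 for Ecrg4. Col3a1 was lower at -7.93, with Gja1, a gap junction protein, at -7.74, Postn at -7.41, S100a6 at -7.39, Cdh11 at -7.34 and Lyz2 at -7.31. Ptgs2 (-7.28), Igf2 (-7.28), Lgals3 (-7.20), Ctsz (-7.04), Acta2 (-6.97) and Ahnak (-6.92) followed, though another Ahnak probe set differed by 0.16.

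Of 11865 genes above the floor, 1151 were apart in iNSC, 163 higher and 988 lower, so that 85.8% were lower. After quantile normalization the split was 297 higher and 600 lower, with 66.9% lower, and 763 of the 1151 genes were still apart. Among 453 genes with several probe sets above the floor, all ran the same way in 391, and all were at least 4-fold apart in 167.

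**Figure D2:**
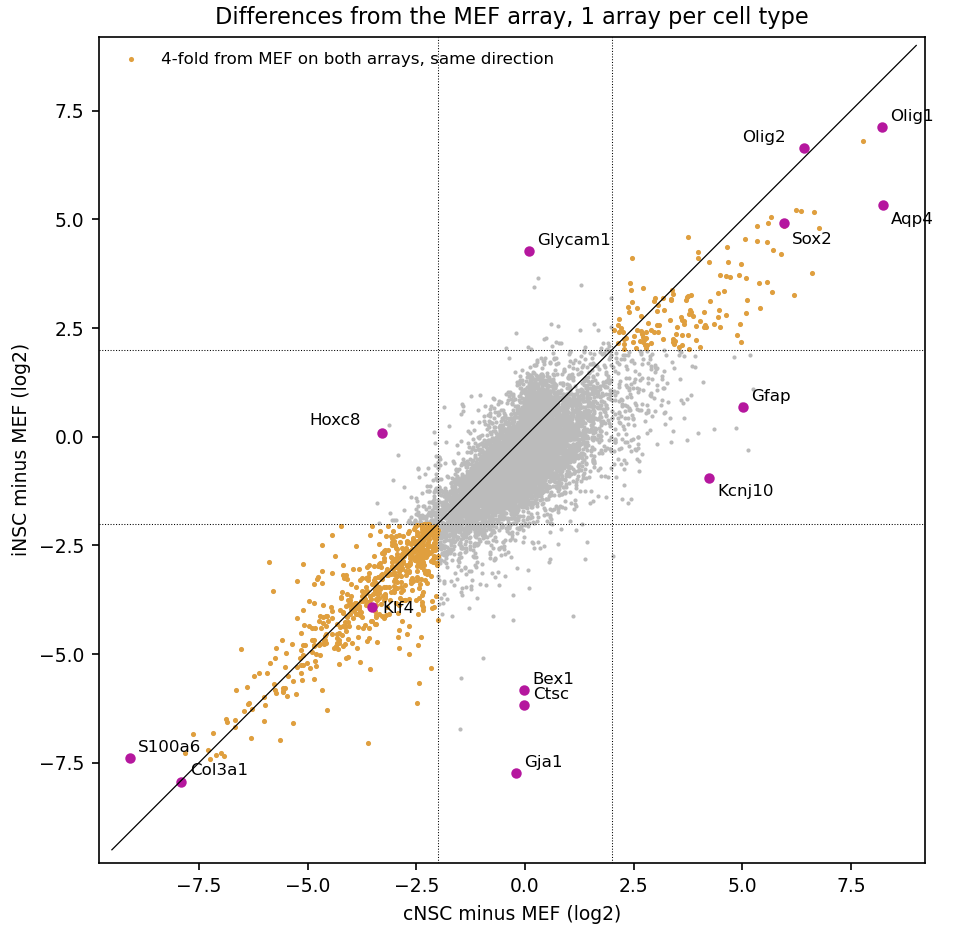
Log2 difference of iNSC from MEF (y axis) against that of cNSC from MEF (x axis), 1 point per gene for 12273 genes at or above the floor, with orange points 4-fold from MEF in the same direction on both arrays. Olig2 lies near the diagonal at 6.43 and 6.63, while Gja1 and Gfap lie far below it.

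Neural stem cell and radial glia genes were higher on both stem cell arrays more often than lower. Of 26 measured, 11 were higher and 1 lower in iNSC, and 14 higher and 1 lower in cNSC, with list medians of 0.74 and 2.24, both at percentile 100.0 of the random lists. Olig2, Ncan, Rfx4 and Gpm6a led in both, and Prom1 was the lower member at -3.30 and -3.0. Nes, often used as a marker of these cells, read 4.07, 4.19 and 4.04 on MEF, iNSC and cNSC, below the floor on all 3 arrays. Nes was not apart in any comparison, and neither was Sox1, at 3.54, 3.46 and 3.57.

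Astrocyte genes differed between the stem cell arrays in number. In iNSC 3 of 16 were higher than MEF (Aldoc 6.79, Aqp4 5.33 and Fgfr3 3.70) and Gja1 was lower, and in cNSC 7 were higher and 0 lower, with Gfap at 5.01. The medians were 0.63 and 1.39, both at percentile 100.0. Of 17 oligodendrocyte lineage genes, 3 were higher and 1 lower on either array, Olig1, Olig2 and Sox8 against Pdgfra (-2.40 in iNSC and -2.58 in cNSC), with medians of 0.18 and 0.29 at percentiles 99.5 and 99.5. Of 21 neuronal genes, Gap43 (-5.83 and -4.66) and Nefm (-3.0 and -2.96) were lower on both arrays, with Tubb3 lower in iNSC (-2.18) and Map2 higher in cNSC (2.15), and the medians of -0.30 and -0.09 lay within the central range.

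Fibroblast and mesenchymal genes were the most lower list. Of 31 measured, 28 were lower in iNSC and 25 in cNSC and 0 were higher, with medians of -4.53 and -4.66, both at percentile 0.0. Col3a1 and Postn led on both, followed by Acta2 (-6.97) and Dcn (-5.91) in iNSC and by Lox (-5.93) and Col6a3 (-5.85) in cNSC. TGF-beta response genes were lower in 10 of 16 in iNSC and 9 in cNSC, with medians of -2.6 and -3.13 at percentile 0.0, including Ccn2 (-6.83 and -7.64), Tgfbi (-5.79 and -5.57) and Inhba (-5.09 and -5.75). Of 8 chondroitin sulfate proteoglycan genes, 4 were higher and 3 lower on both arrays: Ncan, Bcan, Ptprz1 and Cspg5 were higher, while Bgn (-6.81 and -7.18), Dcn and Vcan (-3.53 and -2.6) were lower. Their medians were 0.90 and 1.85 at percentile 100.0, and the iNSC mean of -0.52 had the opposite sign.

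The macrophage, muscle, pericyte, interferon and imprinted lists had medians below those of random lists on both stem cell arrays, with some members not apart. Whether their MEF values came from fibroblasts or from other cells in that culture was not tested. Macrophage genes were lower in 8 of 16 on both arrays, with medians of -2.10 and -2.21 at percentile 0.0, as in Lyz2, Tyrobp (-4.17 and -3.96) and C1qa (-3.87 and -3.90). Skeletal muscle genes were lower in 6 of 18 on both, with medians of -1.28 and -0.82 at percentile 0.0, and Acta1 at -4.22 and -2.0. Pericyte and smooth muscle genes were lower in 3 of 12 on both, with medians of -1.32 and -0.95 at percentiles 0.01 and 0.0. Actg2, at -4.14 and -3.43, led that list. Interferon and antigen presentation genes were lower in 9 of 16 on both, with medians of -2.50 and -2.05 at percentile 0.0, and Usp18 at -4.91 and -5.16. Imprinted genes were lower in 11 of 18 in iNSC and 10 in cNSC, with medians of -2.45 and -2.63 at percentile 0.0, and Igf2, Grb10 (-6.50 and -6.88) and Rian (-5.83 and -6.64) led.

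Cholesterol synthesis genes were higher in 2 of 15 in iNSC (Idi1 2.6 and Nsdhl 2.47) and in 11 in cNSC (Lss 3.72, Idi1 3.66 and Insig1 3.01), with medians of 0.99 and 2.41 at percentile 100.0. Hybridization control scaling removes the control means, 1.17 for cNSC minus MEF and -0.13 for iNSC minus MEF. Insig1 and smaller cNSC differences then fall under 4-fold, while Lss, Idi1 and the iNSC calls stay. The percentiles are unchanged by it. EGF and FGF response genes were higher in 3 of 16 and lower in 1 on both arrays, with medians of 0.49 and 0.64 at percentiles 100.0 and 99.99, Fgfr3 at 3.70 and 4.63 and Dusp4 at -2.28 and -3.19. Notch signalling genes were higher in 4 of 15 and lower in 1 in iNSC, and higher in 5 in cNSC. Their medians were -0.11 at percentile 89.6 and 0.76 at percentile 99.99, with Dll1 at 2.69 and 3.34, and Hey1 at 2.19 and 3.44. The iNSC mean of 0.25 had the opposite sign to its median.

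Cell cycle inhibitors and p53 targets lay below the random lists in iNSC and within their central range in cNSC. Of 12, 2 were higher (Cdkn2a 4.03 and Cdkn2c 3.20) and 6 lower (among them Cdkn1c -4.57 and Phlda3 -2.75), with a median of -1.70 at percentile 0.03. In cNSC 1 was higher (Cdkn2a 4.24) and 1 lower (Cdkn1c -4.20), with a median of -0.11 at percentile 64.2. The G2 and M phase list had 0 of 19 apart on either array, with medians of 0.20 at percentile 100.0 in iNSC and 0.07 at percentile 90.1 in cNSC, and Nusap1 at 1.46 and 1.26. The S phase list had 0 of 19 apart, with medians of -0.55 and -0.30 within the central range.

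In values as deposited, genes lower in cNSC than in MEF were shared by iNSC more often than genes higher in cNSC. Of 709 genes lower in cNSC than in MEF, 595 (83.9%) were also lower in iNSC and 608 were within 2-fold of cNSC, and the median gene had 99.9% of the cNSC difference. Of 334 genes higher in cNSC, 134 (40.1%) were also higher in iNSC, 106 were within 2-fold of cNSC and 109 within 2-fold of MEF, with a median of 54.6% of the cNSC difference. Of the 709 lower genes, 269 read below the floor on both stem cell arrays, where nearness to cNSC is set by the bottom of the scale. Among genes whose dimmer array of cNSC and MEF reached the floor, 296 of 370 lower genes (80.0%) and 74 of 221 higher genes (33.5%) were shared, with medians of 103% and 51.7% of the cNSC difference. Independent lists would share 57.1 lower and 4.44 higher genes. The differences of iNSC and cNSC from MEF correlated across 12273 genes, which are not independent replicates, with r = 0.82 and rho = 0.73. Unchanged cells simulated against the same MEF array gave a mean r of 0.50, with at most 2 shared lower and 1 shared higher genes in any of 100 simulations. The simulated noise was 0.41 log2 units per array. It was taken from the spread of iNSC minus cNSC differences, since no replicate measured the spread between cultures. Equal noise on every array gives an r near 0.50 by construction, so that value was given in advance. With noise this small against the call threshold of 2 log2 units, few shared calls were given in advance too. The simulated r, counts and covariance hold for this noise only. They do not measure how many shared calls came from the shared array. The covariance was 1.14 against 0.17 in the simulation, a difference of 0.97, and part of the excess may come from the shared array. Hybridization control scaling put the shared shares at 33.0% for lower and 73.4% for higher genes.

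Across 17097 genes the iNSC and cNSC arrays were the nearest pair, with Pearson's r = 0.953 and Spearman's rho = 0.937. MEF and iNSC gave 0.885 and 0.875, and MEF and cNSC gave 0.886 and 0.893. Genes are not independent replicates, so no p-value is given.

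**Figure D3:**
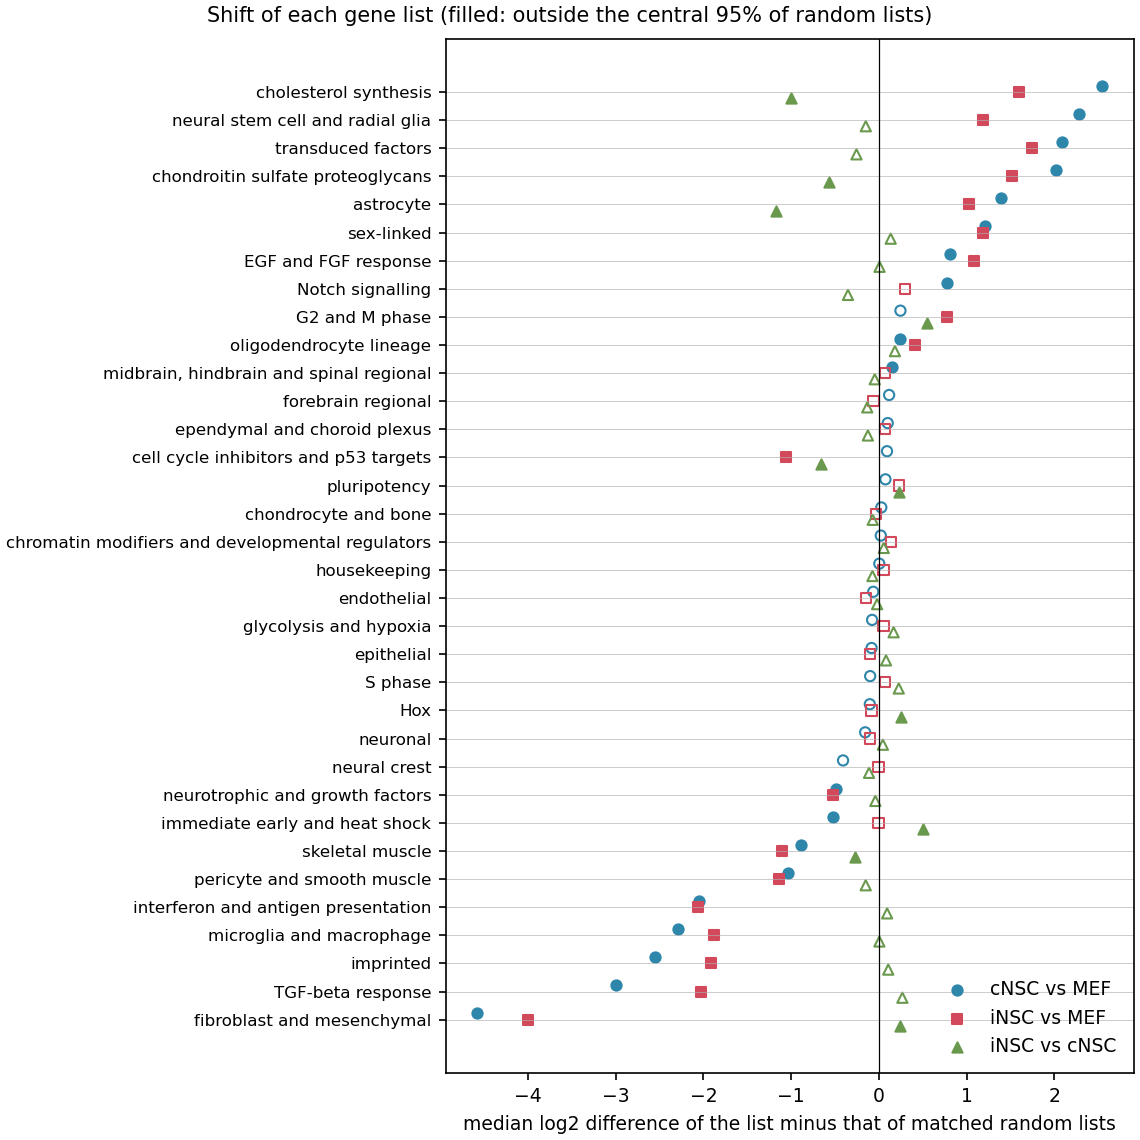
Median log2 difference of each of the 34 gene lists minus that of matched random lists (x axis), with 1 row of points per list and 1 marker per comparison; filled markers lie outside the central 95% of the random lists. The fibroblast list lies farthest left for both stem cell arrays against MEF, and the astrocyte and cholesterol lists lie left of 0 for iNSC against cNSC.

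Comparing iNSC with cNSC asked what still set the induced cells apart. Gja1 read 3.80 in iNSC against 11.33 in cNSC and 11.54 in MEF, and its 5 probe sets above the floor were lower in iNSC by between -0.97 and -7.53. Ctsc was lower at -6.17, Bex1 at -5.81, Ramp1 at -5.43, Ifitm3 at -5.23 and Kcnj10, a potassium channel of astrocytes, at -5.17. Il33 (-4.67), Gfap (-4.33), Hspb8 (-4.21), Scrg1 (-4.21), Wrap53 (-4.17) and Sparcl1 (-4.15) followed, though other probe sets of Wrap53 and Ramp1 differed by 0.05 and -0.07. Glycam1 was the most higher at 4.17, then Rps6ka6 at 3.39, Hoxc8 at 3.36, Grik3 at 3.22, Abracl at 3.0 and Stc2 at 2.57. Miga1 (2.55), Cdon (2.49), Zfp979 (2.47), Tenm3 (2.24), Lmo3 (2.22) and Slc38a1 (2.21) completed the list, and another Cdon probe set differed by -0.10.

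Of 11668 genes above the floor, 293 were apart, 23 higher and 270 lower in iNSC. Several probe sets were above the floor for 134 of these. All ran in the same direction in 111 of the 134, and all were at least 4-fold apart in 19. Quantile normalization gave 52 higher and 160 lower, and scaling to the hybridization controls turned the split to 536 higher and 35 lower, with a median of all genes of 1.04 and 58 of the 293 genes still apart. The 24 named genes, picked as the largest differences, stayed 4-fold apart in the same direction under either of these scalings. The second adds 1 constant that can only widen the higher ones. It is also too small to bring the lower ones, at -4.155 or beyond, under 4-fold, so that outcome was given in advance. With the mean of probe sets 19 of the 24 were still 4-fold apart, and without the _x_at, _s_at and _a_at probe sets 20 of the 22 left were, with 21 in the same direction.

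**Figure D4:**
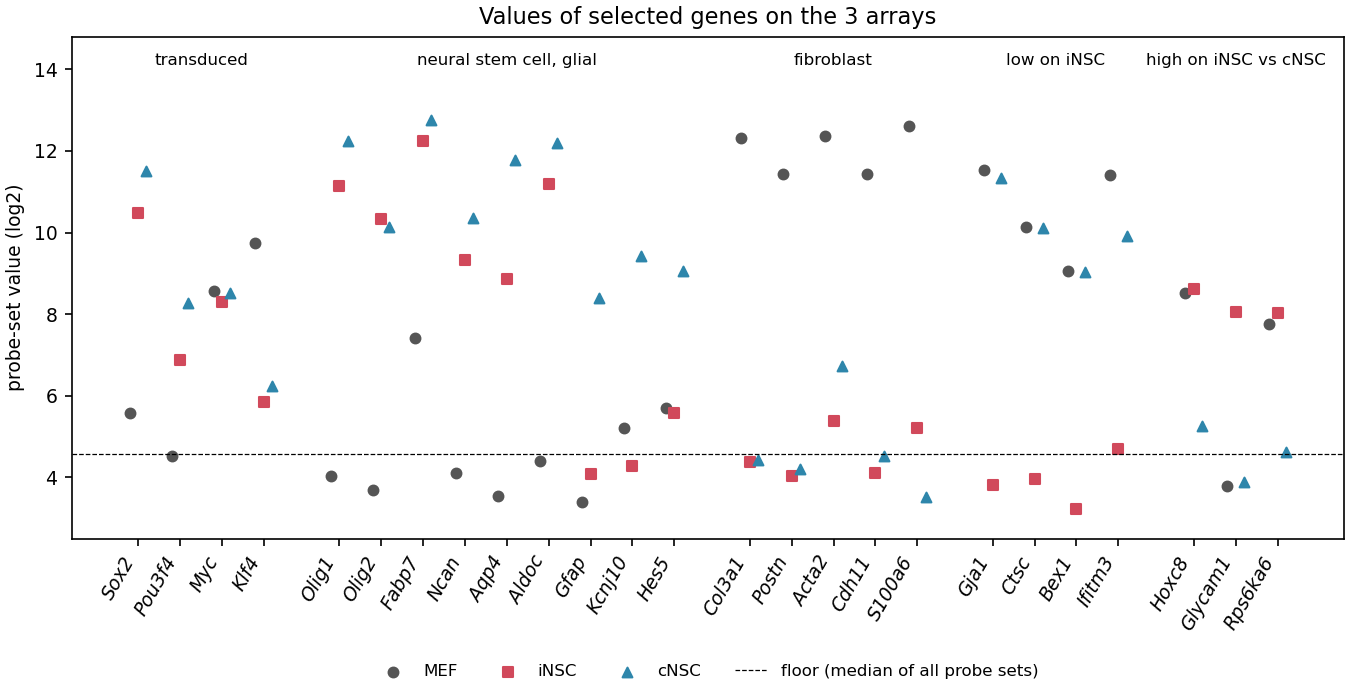
Log2 probe-set value (y axis) of selected genes (x axis) on the MEF, iNSC and cNSC arrays, 1 point per array, with the floor as a dashed line at 4.57. Gja1 reads 3.80 on the iNSC array and above 11 on the others, and Hoxc8 reads 8.61 on iNSC, 8.53 on MEF and 5.25 on cNSC.

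Astrocyte genes were lower in iNSC than in cNSC in 6 of 16, with 0 higher and a median of -1.49 at percentile 0.0. Gja1, Gfap, Aqp4 (-2.90) and S100b (-2.66) led. Hybridization control scaling removes the control mean of -1.30 from every difference of iNSC from cNSC. Medians and calls of all lists move with it, while percentiles stay. Aqp4, S100b, Apoe (-2.185) and Clu (-2.02) then fall under 4-fold, and Gja1 and Gfap do not. Cholesterol synthesis genes had a median of -1.41 at percentile 0.0, with 2 of 15 lower, Lss (-2.85) and Mvd (-2.29). Cell cycle inhibitors and p53 targets had a median of -1.08 at percentile 0.16, with Trp53inp1 lower at -2.29 and Cdkn1a at -1.93 not apart. Chondroitin sulfate proteoglycan genes had a median of -0.97 at percentile 1.56 with 0 of 8 apart, and skeletal muscle genes -0.47 at percentile 2.0 with Acta1 lower at -2.22. The chondroitin list fell within the central range without the _x_at, _s_at and _a_at probe sets, and the muscle list did with the mean of probe sets or members above the floor.

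Of 26 neural stem cell genes 3 were lower in iNSC than in cNSC (Gfap, Hes5 -3.47 and Sox9 -2.43, with another Sox9 probe set at 0.28), with a median of -0.48 at percentile 12.4. Hox genes lay above the random lists, with a median of 0.02 at percentile 99.5 and Hoxc8 and Hoxd8 (2.01) higher but Hoxd10 (-2.41) and Hoxb6 (-2.09) lower. G2 and M phase genes had a median of 0.12 at percentile 100.0 with 0 of 19 apart. Fibroblast genes had a median of -0.11 at percentile 98.0 with 2 of 31 lower (Ddr2 -4.09 and Col5a2 -3.17), but 18 of the 31 reached the floor, and the list fell within the central range after quantile normalization or without the _x_at, _s_at and _a_at probe sets. Immediate early and heat shock genes had a median of 0.10 at percentile 99.95 with 0 of 15 apart and a mean of -0.11. Pluripotency genes had a median of 0.10 at percentile 97.6 with 0 of 15 apart and 4 of 15 reaching the floor. They fell within the central range with either of those settings or with members above the floor, and turned to the other side of random lists with the mean of probe sets. Regional genes of the brain differed in single members: Otx2 was -3.09 and En2 -3.67 in iNSC against cNSC. In all, 18 of 34 lists lay outside the central 95% for iNSC against MEF, 19 for cNSC against MEF and 10 for iNSC against cNSC.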

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

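Both results here were chosen after their values were seen. Control RNA is not part of the cells' own expression, so its probe sets were not counted as genes. The hybridization controls entered gene comparisons only where values were scaled to them. The 18 hybridization control probe sets were higher on the cNSC array than on the MEF array, the negative control, by a mean of 1.17 log2 units, with 18 of 18 higher. The 24 poly-A spike control probe sets were higher on cNSC by a mean of 1.30, with 24 of 24 higher.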

How the results depend on the processing

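Scaling to the hybridization controls and the restriction to genes above the floor on both cNSC and MEF were chosen after seeing the data. Where values moved, the cause was not tested, except that thresholds of 2-fold and 8-fold admit more and fewer genes by construction. Genes apart for iNSC against MEF, cNSC against MEF and iNSC against cNSC numbered 3995, 2921 and 2098 at 2-fold and 471, 476 and 57 at 8-fold. With the mean of all probe sets, iNSC against cNSC gave 180. Hybridization control scaling gave 2545 for cNSC against MEF and 571 for iNSC against cNSC, where the larger count moved from the lower to the higher side. That shift adds 1 constant to every difference, so the genes counted higher are other genes, and 58 of the 293 kept their call. The share of genes higher in cNSC that were also higher in iNSC was 34.9% with the mean of probe sets, 51.9% with quantile normalization, 34.3% at 8-fold, 73.4% with hybridization control scaling and 33.5% above the floor on both arrays. The share for lower genes was 79.1% with quantile normalization, 80.1% with median centring, 88.0% at 2-fold, 33.0% with hybridization control scaling and 80.0% above the floor on both arrays. Correlations for MEF with iNSC, MEF with cNSC and iNSC with cNSC were 0.818, 0.811 and 0.930 over genes above the floor, 0.897, 0.903 and 0.952 over all probe sets, and 0.872, 0.875 and 0.947 without the _x_at, _s_at and _a_at probe sets, and iNSC with cNSC stayed the nearest pair in each. Single results that turned were Wrap53 for iNSC against cNSC, 0.048 without those probe sets, and the pluripotency list, -0.0483 relative to random lists with the mean of probe sets. Of the 18, 19 and 10 lists outside the central 95%, 17, 19 and 8 stayed on their side under quantile normalization and with members above the floor, 16, 17 and 8 with the mean of probe sets, and 18, 17 and 7 without the _x_at, _s_at and _a_at probe sets. The lists lost were growth factors and sex-linked genes for iNSC against MEF, midbrain, hindbrain and spinal, sex-linked and immediate early genes for cNSC against MEF, and pluripotency, skeletal muscle, fibroblast and chondroitin genes for iNSC against cNSC. Median centring and hybridization control scaling add 1 constant per array, so they cannot move lists against random lists. Leaving out the floor altered no count of genes apart, an outcome given in advance. The lowest value on any array, 2.63 on iNSC, lay below the floor by less than the call threshold. The floor could therefore remove no call, and this alternative does not test detection. No paired analysis was possible because each group has 1 array, and for that reason no array could be left out in turn. Signal over background limits dim genes: 47.7% of probe sets on the iNSC array reached the floor, against 50.6% on MEF and 51.7% on cNSC.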

Other observations

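Of the tests below, those of scale, background, RNA degradation and residual fibroblasts were chosen after the results were seen, and the test of other probe sets before. The tests of scale were revised more than once after their values were seen, and gaps are now read against the 2 log2 units that define the genes. Intervals given with these tests treat genes as independent, which they are not. They hold no variation between arrays or cultures, so each reading covers these 3 arrays only. Xist, the RNA of the inactive X chromosome, read 10.71 in MEF, 6.46 in iNSC and 6.18 in cNSC, and Kdm5d, a Y-linked gene, read 5.96, 6.94 and 7.47. The 4 sex-linked genes had medians of 0.46 and 0.96 for iNSC and cNSC against MEF, at percentiles 98.5 and 98.1. Their means of -0.59 and -0.28 had the opposite sign, and the median was -0.32 at percentile 66.0 for iNSC against cNSC. Xist and Kdm5d, both in this list, ran opposite ways against MEF, so the list median gives no direction for sex-linked genes as a whole. With the mean of probe sets this list fell within the central 95% in both comparisons against MEF. Hmga2 was lower than MEF by -4.17 in iNSC and -4.44 in cNSC, the 1 lower gene of 10 chromatin and developmental regulators, whose medians of -0.44 and -0.10 lay at percentiles 72.5 and 53.6. Ier3 was -6.15 and -6.38 and Hspb1 -5.26 and -4.81, within immediate early and heat shock medians of -0.57 and -0.66 at percentiles 48.4 and 0.99, the latter within the central 95% without the _x_at, _s_at and _a_at probe sets. Mdk was -4.60 in iNSC and -2.91 in cNSC and Igf1 -2.85 and -2.45, in a growth factor list with medians of -0.82 and -0.45 at percentiles 1.16 and 0.40. In iNSC the growth factor list fell within the central 95% with the mean of probe sets, quantile normalization or members above the floor.

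Hox genes against MEF had 1 of 34 lower in iNSC (Hoxd13 -3.55) and 3 in cNSC (Hoxd13 -3.65, Hoxc8 -3.28 and Hoxa10 -2.46), with medians of -0.32 and -0.05 at percentiles 23.8 and 7.55. Emx2 was -4.07 in iNSC and -2.46 in cNSC, and Otx2 was 2.70 higher in cNSC; forebrain medians were -0.13 and 0.21 at percentiles 30.1 and 97.1. Midbrain, hindbrain and spinal genes had medians of -0.07 and 0.20 at percentiles 71.8 and 97.55, with En2 2.24 higher in cNSC, and lay within the central 95% in cNSC with the mean of probe sets or without the _x_at, _s_at and _a_at probe sets. Neural crest medians were -0.43 and -0.41 at percentiles 49.1 and 5.00, with Sox8 at 5.05 and 5.66, Snai2 at -3.09 and -4.66 and a cNSC mean of 0.31. Pluripotency genes had 0 of 15 apart, with medians of 0.17 and 0.17 at percentiles 96.8 and 89.5. Medians in iNSC and cNSC were -0.20 and 0.09 for chondrocyte and bone genes with Col2a1 at -3.29 and -2.63, -0.26 and 0.01 for endothelial genes with Flt1 at -2.31 and -1.82, and -0.25 and 0.00 for epithelial genes with Krt18 at -3.33 and -3.01. They were -0.05 and 0.21 for ependymal and choroid plexus genes with 0 of 12 apart, -0.47 and -0.18 for glycolysis and hypoxia genes with Hk2 at -2.44 and -2.72, and -0.46 and -0.13 for housekeeping genes with Gusb at -2.23 and -1.43, all within the central 95%. Means had the opposite sign in cNSC for the chondrocyte (-0.04), endothelial (-0.11) and epithelial (-0.46) lists.

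In values as deposited, the share of lower genes was larger for iNSC than for cNSC against MEF, by 17.9 percentage points. Raising all values below the floor to the floor left 18.9 points. Raising all values below the brightest background probe set of any array, 7.73, to that value left 31.8 points (95% bootstrap interval over genes 25.9 to 38.1). In iNSC 178 genes were then apart, 16 higher and 162 lower, and in cNSC 82 were higher and 119 lower. For these bright genes, this argues against lower background on the iNSC array as the whole cause. It does not cover the dimmer genes that lost their call. The scale of the iNSC array can also lower its count of higher genes, so the rise in points is not read further. Quantile normalization, which equalizes the arrays by construction, left 7.08 points (4.59 to 9.66). This interval spans the bound set for a scale effect, so scale and a real difference cannot be told apart. Scaling to the hybridization controls turned the order, with 81.87% lower for iNSC and 94.97% lower for cNSC against MEF. That scaling lowers every cNSC difference from MEF by a constant, so a rise in the cNSC share was given in advance. Which scaling is right is not known. The Actb control had a 3-prime minus 5-prime difference of 1.04 on iNSC, 0.42 on MEF and 0.69 on cNSC. The Gapdh control gave 0.41, 0.10 and 0.24 in the same order. Both were largest on iNSC, and without positions of the other probe sets RNA degradation stays open. No biological explanation was tested.

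Genes at least 4-fold lower in iNSC than on both other arrays numbered 75, among them Gja1, Ctsc, Bex1 and Ifitm3. After quantile normalization the median of the smaller gap was 2.01 (95% bootstrap interval 1.90 to 2.16) against 2.42 before, an interval that spans the threshold, and 38 of the 75 (50.7%) stayed 4-fold lower, so the iNSC array's scale and lower expression cannot be told apart. Scaling to the hybridization controls left a median gap of 1.30 (0.97 to 1.58), under the threshold, with 19 of the 75 (25.3%) still 4-fold lower. The controls differed by a mean of -1.30 for iNSC minus cNSC, and the scaling narrows every gap from cNSC by that 1 constant. With a median gap of 2.42 before, the fall under the threshold was given in advance. It therefore cannot decide whether the scale of the cNSC array is the cause, and which scaling is right is not known. Of 37 genes with another probe set above the floor, 18 (48.6%, 95% Wilson interval 33.4 to 64.1) had the others at least 2-fold lower too, so failure of single probe sets cannot be told apart from lower expression. No biological explanation was tested.

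Genes at least 4-fold higher in iNSC than in cNSC and within 2-fold of MEF numbered 10, and the 4 that stayed in this class after quantile normalization were Hoxc8, Cdon, Gas7 and Fscn1, the last pair chosen after their values were seen. Fibroblasts left in the culture are argued against, since 29 fibroblast list genes kept a median of 3.89% of their MEF level (2.56 to 7.52) where these genes would need a median of 151%. The rule that selected the genes sets a high need in advance, 43.3% for the lowest (Fscn1). The argument therefore rests on the low level of the fibroblast list. Quantile normalization widened the gap from cNSC in 10 of the 10, to a median of 2.69 (2.58 to 3.40) against 2.20 before, which argues against the scale it removes as the cause of that gap. The iNSC array was dimmer than cNSC at the 75th percentile (5.97 against 6.44). The widening thus follows from the arrays' distributions, and the 10 genes are not separate evidence. It left 4 of the 10 (40.0%, 95% Wilson interval 16.8 to 68.7) within 2-fold of MEF, too few to decide, so for the likeness to MEF scale cannot be told apart from a real likeness. Likeness to MEF was the rule that selected these genes, and no biological explanation was tested.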
